A study of Mus musculus with 5 samples.

How the data were processed

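Mammary epithelial cells of 4-week-old mice were profiled on 5 Affymetrix arrays, 2 from conditional knockout mice carrying an MMTV-Cre transgene and floxed Mmp14 alleles and 3 from littermates with the floxed alleles and no Cre. Per the labels' protocols, the cells came from inguinal glands without the lymph node, were freed with collagenase and separated from stroma by differential centrifugation, and cDNA was made from 10 ng of total RNA with a whole-transcript kit. The deposited values are log2 signals per probe set; RMA (background correction, quantile normalisation and median-polish summary of the probes of a set) and limma are named in the submitters' processing notes without a version. The array model, the library files behind the summary and the genome build are not given in the sources used here, so no coordinates are printed. The labels do not say whether each array holds 1 mouse or a pool, so p-values measure the spread between these 5 samples.

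The table holds 41345 probe sets. The platform annotation names 1 gene symbol for 23521 of them and several symbols for 1814, and it does not list the other 16010, which are unnamed here. Probe sets with several symbols or none were left out of the gene tests. For the 1082 genes with several probe sets the one with the highest mean over the 5 arrays was kept, which set 1341 probe sets aside and left 22180 genes. Symbols in the gene lists that the annotation writes differently were looked up as synonyms in a RefSeq gene table of GRCm38.p6, used only for names and for which genes are neighbours. The array medians over all probe sets lay between 4.24 and 4.29 log2 units. No detection calls were used, so low signals cannot be told from background, and the number of arrays limits the precision.

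Many values are exactly equal between arrays. To 6 decimals, 68.8% of the tested genes had the same value on at least 2 of the 5 arrays, and 12.8% had the same value on all 3 wild-type arrays. The median residual SD was 0.151 log2 units for the 6930 genes with 5 different values and 0.0256 for genes with 4 equal values. Such ties lower the estimated spread of a gene and can make a small difference pass a test.

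Differences are knockout minus wild type. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. The SE given with a difference is limma's moderated SE. Gene lists were tested with camera from the same package, with a preset inter-gene correlation of 0.01 and adjustment over the 47 of 49 lists that had at least 5 measured members. The lists were written before the data were examined. They cover the cell types of the gland, cells that a collagenase preparation can carry over, matrix and protease genes, signalling, metabolism, stress and RNA quality. They hold 960 genes, of which 851 were measured. The genes named in the text follow a rule set at the same time. It takes Mmp14, then 12 genes per direction, and per list discussed up to 4 members with the largest moderated t. Fewer than 4 are named for many lists, and members whose direction turned under an alternative were among those left unnamed after their values were seen. The 12 are those past the test with no overlap between the groups. Where fewer pass, they are filled by the smallest unadjusted p among genes whose groups do not overlap, whose mean lies above the median gene and which are not numbered gene models, clones, small RNAs, olfactory receptors or antigen receptor segments. Genes named outside this rule are said to be chosen after their values were seen.

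The procedure was tested on simulated data with the spread of these arrays and the same 2 against 3 arrays. Over 20 simulations of 22180 genes, the gene test called 38.1% of genes changed by 0.5 log2 units, 63.5% of those changed by 1, 82.3% of those changed by 2 and 92.3% of those changed by 3, and 187 of 439600 unchanged genes. A list shifted by 0.25 log2 units was called in 20 of 20 simulations. The simulated genes varied independently of each other, which genes of 1 tissue do not. Their values had no exact ties but took the residual SDs of all genes, tied ones included, shuffled over genes. The arrays themselves gave 288 genes at an unadjusted p under 0.05 in limma's test, where 1109 are expected with no difference. The simulated shares therefore do not give the share of real changes that would be called here.

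The array numbers in the labels fall in 2 runs of consecutive numbers. Run 1 holds knockout 1, wild type 1 and wild type 2, and run 2 holds wild type 3 and knockout 2. Nothing in the labels says what a run stands for. It was treated as a possible batch, with differences given within each run and with the run as a fixed or random block. The other alternatives were quantile normalisation and median centring of the arrays, leaving out genes under the 40th percentile of signal, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, a block for the replicate number, each array left out in turn, all probe sets, other thresholds, and camera with an estimated correlation or the fry test for the lists. Figures were drawn with matplotlib 3.10.9.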

Results

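MMP14 is a membrane-anchored metalloproteinase that cleaves matrix proteins at the cell surface. The arrays asked how its loss in the epithelium alters gene expression of the developing mammary gland at 4 weeks of age. Signals of 22180 genes were compared between 2 arrays of mice labelled as epithelial Mmp14 conditional knockouts and 3 arrays of floxed littermates without Cre, called wild type here. Mean ± SD refers to n = 2 knockout and n = 3 wild-type arrays throughout, and values are log2 units.

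Mmp14 itself (probe set 17300279) was not separated between the genotypes. Its signal was 7.63 ± 0.50 in the knockout and 8.19 ± 0.47 in the wild type, a difference of -0.56 ± 0.39 (SE; limma adjusted p = 0.919). The array of knockout 1 read 7.98 and that of knockout 2 read 7.28, against 8.15, 8.67 and 7.75 on the wild-type arrays, so knockout 1 lay above wild type 3. Within the runs of array numbers the difference was -0.43 in run 1 and -0.46 in run 2, the latter from 1 array per genotype. It was -0.21 without knockout 2 and -0.91 without knockout 1. Where the probes of this set lie relative to the floxed exons is not given in the sources used here, and stromal cells left in a preparation also carry Mmp14, so the signal does not settle the genotype labels.

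The other metalloproteinases and the matrix showed no called difference either. Mmp13, an interstitial collagenase, was 5.87 ± 0.05 in the knockout and 5.64 ± 0.12 in the wild type, and both knockout arrays lay above all wild-type arrays. Mmp2, the gelatinase that MMP14 activates, was 8.45 ± 0.20 against 7.99 ± 0.37, and Mmp3, stromelysin 1, was 8.58 ± 0.30 against 7.81 ± 0.66. Both had overlapping groups. Of the 20 measured secreted metalloproteinases and their inhibitors, 15 had a higher mean in the knockout and 0 passed limma's test, with a median of 0.03 and a camera adjusted p = 0.145. The 5 membrane-type metalloproteinases (median -0.01, camera adjusted p = 0.782), the 17 ADAM and ADAMTS proteases (median -0.03, adjusted p = 0.970) and the 22 partners and reported substrates of MMP14 (median 0.00, adjusted p = 0.952) did not pass. Among these substrates Tgm2, a transglutaminase, was lower by 0.54 ± 0.33 (SE) in the mean and Lum, a collagen-binding proteoglycan, was higher by 0.41 ± 0.23.

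**Figure D1:**
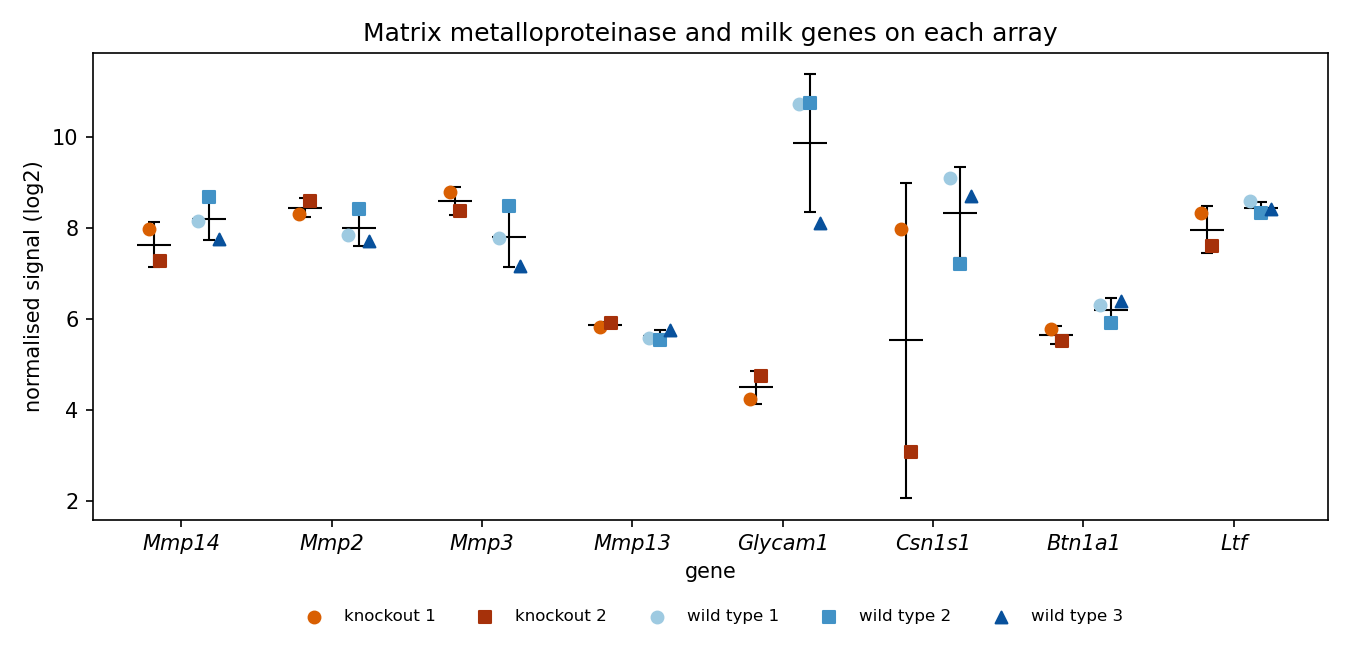
Normalised log2 signal of 8 genes (x axis) on each array, with the mean (bar) and SD (whiskers) of the 2 knockout and 3 wild-type arrays. Mmp14 on the array of knockout 1 (7.98) lies among the wild-type values, while Glycam1 is at 4.24 and 4.76 on the knockout arrays and between 8.10 and 10.74 on the wild-type arrays.

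Over all genes, 0 of 22180 differed between the genotypes at limma's adjusted p of 0.05, and the smallest adjusted p was 0.919. At an unadjusted p under 0.05 there were 288 genes, 156 higher and 132 lower in the knockout, where 1109 are expected with no difference at all. The groups did not overlap for 584 genes higher in the knockout (2.6% of genes) and 621 lower (2.8%). Tied values make such a separation rarer. Among the 6930 genes with 5 different values it held for 5.4% and 5.7%, where chance gives 10% in each direction. The median SE of a difference was 0.0699, and 81 genes had means 1.5-fold or more apart. Leaving out knockout 1 gave 1757 called genes and leaving out knockout 2 gave 835, of which 86.7% and 93.5% had tied wild-type values, as 43.9% of all genes have. Of these calls, 156 and 40 were genes with 5 different values. Fitted on their own, a restriction chosen after seeing the data, those 6930 genes gave 0 calls with either array left out, under another estimate of the spread.

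The 12 genes named per direction did not pass limma's test (adjusted p = 0.919 for each). Their groups did not overlap because the rule took only such genes. The largest was Glycam1, a mucin-like protein of milk and of lymph node venules, at 4.50 ± 0.37 in the knockout and 9.85 ± 1.52 in the wild type (-5.35 ± 1.03, SE). Its difference was -6.49 within run 1 and -3.34 within run 2. The other lower genes differed by little. Gas2l3, which links actin and microtubules, was at -0.32 ± 0.05, Cep76, a centriolar protein, at -0.21 ± 0.04, Usp12, a deubiquitinase, at -0.20 ± 0.03 and Dgat1, an enzyme of triglyceride synthesis, at -0.18 ± 0.03. Dcbld1 (-0.17), Mpp7 (-0.16), Marveld3 (-0.15), Tbck (-0.14), Psmd10 (-0.12), Pa2g4 (-0.11) and Rnf13 (-0.09) completed this side. The sign of Mpp7 turned when the probe sets of a gene were averaged.

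On the higher side, Rpph1, the RNA component of RNase P, was 9.81 ± 0.00 in the knockout and 9.28 ± 0.08 in the wild type, a difference of 0.53 ± 0.05 (SE). Slc25a37, a mitochondrial iron importer, stood at 0.49 ± 0.08, Smok4a at 0.31 ± 0.03, Tbc1d2, a regulator of Rab GTPases, at 0.30 ± 0.05 and Kat2a, a histone acetyltransferase, at 0.29 ± 0.05. Paip2b (0.20), Phlda1 (0.20), Akt1 (0.16), Tusc1 (0.15), Prss48 (0.13), Gosr1 (0.07) and Ankrd13c (0.07) differed less.

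The luminal progenitor and alveolar list shifted down in the knockout, with a median of -0.21 and a mean of -0.82 over 18 measured members (camera adjusted p = 0.00141). The call was lost with an estimated correlation (adjusted p = 0.987). The mean of 17 of the 18 members was lower in the knockout, but none passed limma's test over all genes and none passed adjusted over the list alone. Besides Glycam1, Btn1a1, a milk fat globule protein, was 5.65 ± 0.19 against 6.20 ± 0.26, Ltf, lactoferrin, was 7.96 ± 0.51 against 8.44 ± 0.13, and Csn1s1, a casein, was 5.53 ± 3.46 against 8.34 ± 0.99. The list mean relative to the wild-type mean was -0.47 in knockout 1 and -1.17 in knockout 2. Without Glycam1, left out after seeing the data, it was -0.17 and -0.94, against 0.33, -0.36 and 0.02 on the wild-type arrays, so knockout 1 lay among them. The list of 17 was still called (median -0.18, camera adjusted p = 0.00574; adjusted p = 0.987 with an estimated correlation), but not without knockout 2 (adjusted p = 0.723). For all 18 members the median difference was -0.12 within run 1 and -0.31 within run 2. The call for the 18 was also lost without knockout 2 (median -0.07, adjusted p = 0.621) and without wild type 1 (median -0.16, adjusted p = 0.0776).

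The other 4 lists called by camera shifted by smaller amounts, and no member of them passed limma's test over all genes or adjusted over the list alone. The list of mitochondrially encoded genes shifted up, with a median of 0.09 and all 10 measured members higher in the mean (camera adjusted p = 0.000322; adjusted p = 0.987 with an estimated correlation). Among them ND5 was higher by 0.08 ± 0.03 (SE), ND4L by 0.10 ± 0.05 and COX3 by 0.09 ± 0.05. The median was 0.10 within run 1 and 0.02 within run 2, and the call was lost without knockout 1 (adjusted p = 0.172).

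The list of immediate-early and dissociation stress genes shifted up by a median of 0.08 over 27 members (camera adjusted p = 0.00447; adjusted p = 0.987 with an estimated correlation). Junb was higher by 0.24 ± 0.11 (SE), Ier2 by 0.29 ± 0.14, Zfp36 by 0.19 ± 0.10 and Socs3 by 0.30 ± 0.16. The median was -0.01 within run 1 and 0.41 within run 2. The call was lost without knockout 2 (median 0.04), wild type 1 (median 0.10, camera adjusted p = 0.0776) or wild type 3 (median 0.06, camera adjusted p = 0.199). The median was 0.31 without knockout 1 and 0.18 without wild type 2.

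The DNA replication list shifted down by a median of -0.10 over 26 members (camera adjusted p = 0.00382; adjusted p = 0.987 with an estimated correlation). Mcm3, a subunit of the replicative helicase, was at -0.18 ± 0.11 (SE), Gins2 at -0.26 ± 0.15 and Cdc45 at -0.14 ± 0.09, while Tyms was at 0.05 ± 0.03. The median was 0.00 within run 1 and -0.22 within run 2. The call was lost without knockout 2 (adjusted p = 0.820) or wild type 1 (adjusted p = 0.0776).

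The skin keratinocyte and hair list shifted down by a median of -0.18 over 17 members (camera adjusted p = 0.0436; adjusted p = 0.987 with an estimated correlation), with the hair follicle keratin Krt71 at -0.18 ± 0.11 (SE). Its mean lay 0.59 above the wild-type mean on the array of wild type 1, and without that array the median was 0.00 (adjusted p = 0.909). The median was -0.19 within run 1 and 0.00 within run 2, and with the run as a fixed block the call was lost (adjusted p = 0.0552). It was also lost without knockout 1 (median -0.19) and without knockout 2 (median -0.12). The same held without dim genes (median -0.41, camera adjusted p = 0.175) and with array weights (median -0.21, camera adjusted p = 0.0844), where the median was larger in size. Over all 47 lists, no member passed limma's test over all genes or adjusted over its list alone.

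No other epithelial group passed the test. The 13 hormone-sensing luminal genes had a median of -0.09 (camera adjusted p = 0.476), although Gpx3, a secreted peroxidase, was 6.78 ± 0.58 against 7.74 ± 0.32, and Esr1, the oestrogen receptor, was 6.09 ± 0.03 against 5.96 ± 0.09. The 22 pan-luminal and epithelial genes had a median of -0.04 (adjusted p = 0.801), with the tight junction gene Cldn4 at 0.09 ± 0.03 (SE) and Cldn7 at -0.05 ± 0.03. The 19 basal myoepithelial genes had a median of 0.12 (adjusted p = 0.198), and 14 of them had a higher mean in the knockout. Nrg1, a growth factor, was 8.74 ± 0.40 against 8.38 ± 0.25, and the Notch ligand Jag2 was 4.73 ± 0.05 against 4.69 ± 0.01, while Pcp4, a calmodulin-binding peptide, was 6.88 ± 0.28 against 7.76 ± 0.43. The 33 genes of branching morphogenesis (median 0.01, adjusted p = 0.970), the 17 of epithelial-mesenchymal transition (0.08, adjusted p = 0.142), and the responses to TGF-beta (0.03, adjusted p = 0.801), Notch (0.00, adjusted p = 0.497), Wnt (0.00, adjusted p = 0.404) and oestrogen and progesterone (0.01, adjusted p = 0.970) did not pass. In the Wnt list Wif1, a secreted Wnt inhibitor, was 5.55 ± 0.07 against 5.18 ± 0.24.

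Matrix and adhesion lists did not pass the test. Medians were 0.01 for 26 basement membrane genes (camera adjusted p = 0.977), 0.03 for 26 fibrillar matrix and crosslinking genes (adjusted p = 0.612) and 0.02 for 23 integrin and focal adhesion genes (adjusted p = 0.574). Col6a3, a microfibrillar collagen chain, was lower by 0.39 ± 0.22 (SE) in the mean and Tnc, tenascin C, higher by 0.28 ± 0.20. Itgb8, an integrin chain that activates TGF-beta, was 7.06 ± 0.03 against 7.26 ± 0.15, and Vcl, vinculin, was 9.79 ± 0.01 against 9.76 ± 0.01.

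Lists of markers of non-epithelial cells did not pass the test either. The 19 fibroblast genes had a median of 0.14 (camera adjusted p = 0.295), the 19 endothelial genes -0.07 (adjusted p = 0.378), the 11 pericyte genes -0.03 (adjusted p = 0.952), the 20 adipocyte genes 0.00 (adjusted p = 0.709) and the 12 Schwann and nerve genes 0.08 (adjusted p = 0.404). Medians of the immune lists were -0.10 for macrophages and monocytes (adjusted p = 0.378), -0.11 for T and NK cells (adjusted p = 0.144), -0.06 for B and plasma cells (adjusted p = 0.0809), 0.04 for neutrophils and mast cells (adjusted p = 0.700) and -0.06 for eosinophils (adjusted p = 0.430). Ccr7, a homing receptor of lymphocytes and dendritic cells, was 6.28 ± 0.12 against 6.62 ± 0.21. Endothelial and pericyte means split the knockout arrays, at -0.37 and -0.41 relative to wild type in knockout 1 and at 0.18 and 0.40 in knockout 2. The endothelial mean of wild type 2 was 0.22, above that of knockout 2. Of the endothelial genes, Kdr, a VEGF receptor, was 4.87 in knockout 1 and 5.21 in knockout 2 against a wild-type mean of 5.26. Plvap was 5.89 and 6.57 against 6.64. Neither gene was above its wild-type mean in knockout 2.

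**Figure D2:**
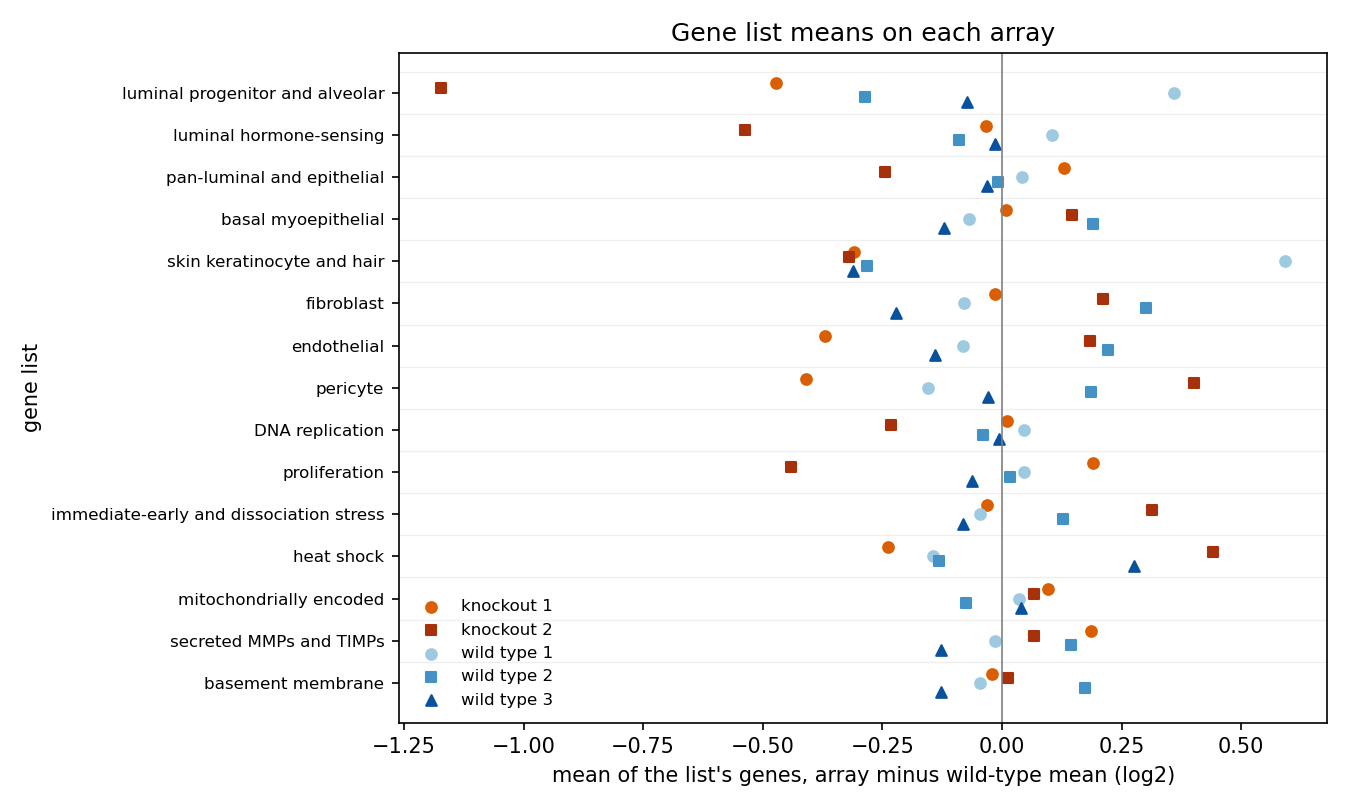
Mean of each gene list (y axis) on each array relative to the mean of the 3 wild-type arrays, in log2 units, for 15 lists. The array of knockout 2 is lowest for the luminal progenitor (-1.17) and proliferation lists (-0.44), and knockout 1 is lowest for the endothelial (-0.37) and pericyte lists (-0.41).

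Proliferation, stress and metabolism lists that were not called had medians between -0.06 and 0.10. These were proliferation (-0.05, camera adjusted p = 0.217), replication-dependent histones (0.00, adjusted p = 0.970), heat shock (0.10, adjusted p = 0.365), unfolded protein response (-0.06, adjusted p = 0.149), apoptosis and p53 (0.00, adjusted p = 0.970), hypoxia (-0.01, adjusted p = 0.497), glycolysis (-0.05, adjusted p = 0.447), respiratory chain (-0.04, adjusted p = 0.150), cholesterol (-0.02, adjusted p = 0.430) and fatty acid synthesis (0.02, adjusted p = 0.920) and cytosolic ribosomal proteins (0.00, adjusted p = 0.920). Proliferation genes split the knockout arrays, with a list mean of -0.44 in knockout 2 and 0.19 in knockout 1. Kif11, a mitotic kinesin, read 5.57 in knockout 2 and 6.14 in knockout 1, against a wild-type mean of 6.16. Birc5, an inhibitor of apoptosis active in mitosis, read 5.59 and 5.83 against 5.84. Neither gene was above its wild-type mean in knockout 1. The interferon-stimulated (-0.03, adjusted p = 0.574), inflammatory cytokine (-0.01, adjusted p = 0.970), antigen presentation (-0.04, adjusted p = 0.801), circadian (0.04, adjusted p = 0.478) and skeletal muscle lists (-0.01, adjusted p = 0.497) did not pass. Of the clock genes, Bhlhe41, a transcriptional repressor, was 8.01 ± 0.10 against 7.46 ± 0.23. In 6 of the uncalled lists, among them basement membrane, pericyte and inflammatory cytokines, the median, the mean and the test differed in sign.

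Pearson correlations across the 22180 genes, which are not independent replicates, ran from 0.990 to 0.996, and the 2 knockout arrays correlated at 0.991 with each other. The first principal component held 45.0% of the variance and set knockout 2 (25.3) apart from the other arrays (-12.5 to 4.63). Knockout 1 lay at -12.0, beside wild type 1. Both arrays of run 2 had the highest scores on this component. The fourth component, with 13.2%, had both knockout arrays (8.46 and 5.27) above the wild-type arrays (-10.7 to 4.54).

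**Figure D3:**
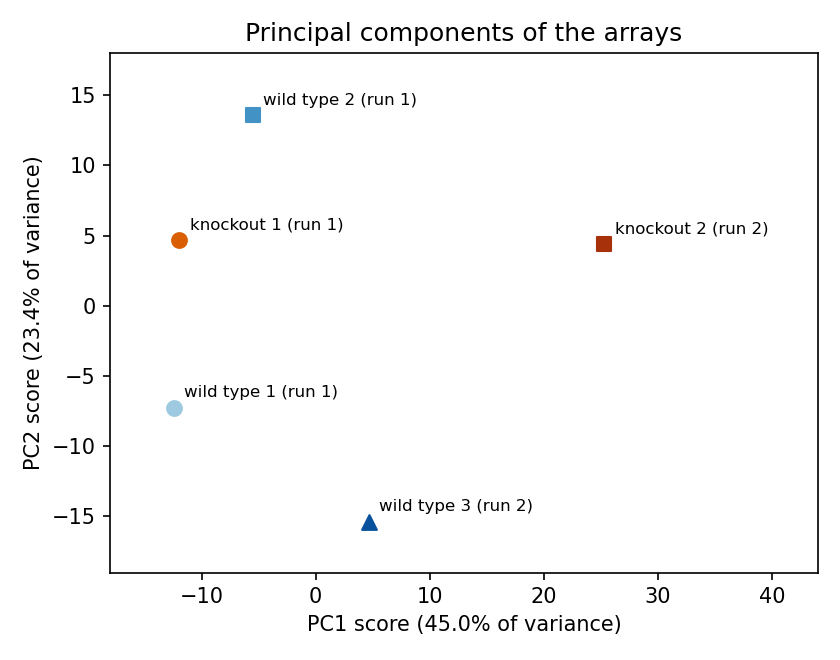
Scores of the 5 arrays on the first (x axis, 45.0% of variance) and second principal component (y axis, 23.4%) over 22180 genes, with the run of array numbers in brackets. Knockout 2 lies apart from the rest at 25.3 on the first component and knockout 1 lies with the wild-type arrays of its run.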

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

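The restrictions to genes with 5 different values and to the arrays of a single run, and the luminal progenitor list without Glycam1, which stayed called, were chosen after seeing the data; the other alternatives were set beforehand. Mmp14 stayed lower in the knockout and uncalled in each, between -0.91 and -0.21 when 1 array was left out and -0.78 with the replicate number as a block. The count of called genes by limma was 0 in run 1 alone and in the alternatives that kept all 5 arrays, including all 41345 probe sets (937 at an unadjusted p under 0.05), an adjusted p under 0.10 and the block for the replicate number, except that 11 passed an unadjusted p under 0.05 with a 1.5-fold difference. Leaving out 1 array gave 0 to 1757 genes, all of the calls without a knockout array (1757 without knockout 1, 835 without knockout 2); the lone knockout array is then assumed to vary like the wild type. Fitted on their own, the genes with 5 different values gave 0 in both cases, under another estimate of the spread. The 5 called lists became 11 with the replicate block, 1 to 14 with 1 array left out, 0 with an estimated correlation, 0 by fry's directional and 0 by its mixed test, and, among genes with 5 different values, 15 without knockout 1 and 8 without knockout 2; the other alternatives stayed within 1.5 times the 5. In run 1 alone 4 lists passed, but 0 of the 5. Of single lists, the immediate-early call was lost with the replicate block (median 0.06, camera adjusted p = 0.0541). The mitochondrially encoded, DNA replication and skin calls were lost among genes with 5 different values (camera adjusted p = 0.0887, 0.119 and 0.119). Their medians there (0.10, -0.14 and -0.20) were no smaller in size than over all members. The median of DNA replication turned to 0.0545 among genes with 5 different values without knockout 2, and that of the immediate-early list to -0.0080 in run 1 alone. Mpp7 turned to 0.0715 with the mean of its probe sets. Named list members were picked from 178 with the largest moderated t of their lists, of which 142 kept their direction in every alternative run and 36 turned in at least 1. The lowest correlation between arrays fell from 0.990 to 0.979 without dim genes. The causes were not tested, apart from the fewer genes or arrays that some alternatives hold. Whether same-numbered arrays are paired cannot be told from their deviations from the group means. These correlated across genes at 0.245 for number 1 and -0.044 for number 2. With 2 knockout arrays the deviations of 1 mirror those of the other, so the values are not separate checks. With no detection calls, low signals limit what dim genes can show.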

Other observations

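The tests of tied values, of casein genes and of the lists over other splits were chosen after the results were seen, and so was what the estimated correlation and the left-out arrays should show for the 5 lists, although those fits were planned. Over all genes, 10 had means at least 2-fold apart with no overlap between the groups, none past limma's test (adjusted p = 0.919 for each); apart from Glycam1 these were chosen after their values were seen. Dmbt1, a mucosal scavenger receptor protein, was at 5.54 ± 0.88 (SD, n = 2) in the knockout and 6.66 ± 0.20 (n = 3) in the wild type, Dcpp2 at 4.60 ± 0.72 against 5.70 ± 0.15, Olfm4 at 4.22 ± 0.69 against 5.52 ± 1.10 and Clca1 at 3.97 ± 0.24 against 5.27 ± 0.83. Epgn, a ligand of the EGF receptor, was at 6.40 ± 0.93 against 7.46 ± 0.34. Wfdc21 and the epidermal keratin Krt1 were high on the array of wild type 1 alone, at 7.29 and 6.94, with all other arrays at 4.37 or less. AF357355, a small RNA, was at 5.01 ± 0.14 against 6.05 ± 0.66, and Glycam1 was the largest.

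The nonagouti gene, which encodes a melanocortin receptor antagonist, was the only one of the 10 that was higher in the knockout. It read 4.04 and 4.10 on the knockout arrays and 2.96, 3.06 and 2.89 on the wild-type arrays, a difference of 1.09 ± 0.06 (SE) with adjusted p = 0.919. The signal is dim. The skin and hair list did not follow this gene, since its mean relative to the wild type was -0.31 and -0.32 on the knockout arrays, -0.28 and -0.31 on wild type 2 and 3, and 0.59 on wild type 1. The 20 measured genes nearest to nonagouti had a median absolute difference of 0.03, at the 8.9th percentile of random runs of 20 neighbouring genes, and the largest was 0.14.

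For 5 lists the direction of the call turned with the knockout array that was left out. Their means on the 2 knockout arrays lay on opposite sides of the wild-type mean. The endothelial mean of knockout 2 (0.18) stayed within the wild-type arrays, below wild type 2 (0.22). Without knockout 1, the proliferation, respiratory chain and pan-luminal lists were called lower in the knockout (medians -0.33, -0.13 and -0.19) and the endothelial and pericyte lists higher (0.22 and 0.35). Without knockout 2, all 5 of these lists passed camera's test in the other direction (0.19, 0.04, 0.09, -0.38 and -0.36). These calls were made with the preset correlation of 0.01, while all 5 arrays gave these lists estimated correlations of 0.463 to 0.888. No list passed with an estimated one, run after they were seen. That form cannot show that the calls rest on correlation. Over all 5 arrays it also raised camera's unadjusted p of the secreted metalloproteinases, estimated at -0.027, from 0.0277 to 0.0957. The luminal progenitor list (-0.46 and -0.07) and the mitochondrially encoded list (0.06 and 0.08) kept their direction both times. The differences of the 2 knockout arrays from the shared wild-type arrays correlated at -0.048 across genes, where simulated unchanged groups against the same controls gave 0.243; the covariance was -0.00159 against 0.00855. Xist read 10.75 to 10.77 on all 5 arrays, and the Y-linked Uty, Eif2s3y and Kdm5d stayed between 2.44 and 2.89. Kdm5d was higher on both knockout arrays than on all wild-type arrays, by 0.09 ± 0.02 (SE; limma adjusted p = 0.919).

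The comparison of genotypes called 0 genes, and so did each of the other splits of the 5 arrays into 2 and 3 (10 of 10 splits with at least as many, highest other 0). Any split has at least 0 calls, so this comparison could not decide. With 10 splits a share under 0.05 cannot be reached either. At an unadjusted p under 0.05 the split by run gave 1710 genes against 288 for genotype. The remaining splits gave 219 to 890 genes. Among these, the splits that pair knockout 2 with wild type 1 and with wild type 2 gave 385 and 787. The count for knockout 2 was thus highest with wild type 3. Run 2 holds only these 2 arrays, and knockout 2 stood apart from all others. A structure by run, a difference of knockout 2 and another likeness of the 2 arrays cannot be told apart. With the run as a block the genotype gave 865 genes at this level and 0 called.

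Calls appeared when 1 knockout array was left out, 1757 without knockout 1 and 835 without knockout 2. Of these calls, 88.9% were genes with an exact tie among the wild-type arrays, as 43.9% of all genes have. Genes with 5 different values made up 7.6% of the calls (196) and 31.2% of all genes. At an unadjusted p under 0.05, 817 of the genes with 5 different values, fitted on their own, passed without knockout 1 and 310 without knockout 2, where 346 are expected with no difference. A candidate explanation is that the summary of probes over few arrays makes equal values, so that a single differing array stands out against a spread near 0. The called genes with 5 different values have no tie of their own, but ties also lower the spread estimate that all genes share. Their cause stays open, and so does a difference of knockout 2 from the wild type. Most genes called in both fits went in opposite directions, so those calls do not show a change shared by the knockout arrays.

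Whether the 5 called lists rest on correlated genes stays open, and no 1 array carries all 5. Without wild type 1 only the mitochondrially encoded call of the 5 held, and that call was lost without knockout 1. With an estimated correlation the smallest adjusted p of the 5 was 0.987, and 1 of the 5 lists passed in the same direction without knockout 2, against 3 without knockout 1. Of the 10 splits into 2 and 3 arrays, 9 called at least 5 lists, with up to 21, and 10 splits are too few for a share under 0.05. Many splits called several times the count of the genotype, so a count of 5 is not particular to the genotype. Why the other splits called so many lists was not tested. An effect of genotype on luminal progenitor genes stays open, since camera called the list (adjusted p = 0.00141) and fry's directional test did not (adjusted p = 0.994).

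Glycam1 was low on both knockout arrays and high on all wild-type arrays. Lymph node venules express it, and the 6 other markers of these venules and of the node with a signal above the median gene had a median difference of -0.23, above the -1 set in advance by more than 2 bootstrap SEs (0.15). That bound was wrong for 3 of the 6 (Ackr1, Selp and Sele), set aside only after the values were seen, because ordinary venules express them too and would hide a small share of node. The other 3 (Cxcl13, Ighm and Cd79a) had a median of -0.43, still above -1, but are too few to decide. Ighm (6.71 and 6.81), Cxcl13 (6.27 and 6.65) and Ms4a1 (4.07 and 3.89) were highest on wild type 1 and 2, while on wild type 3 Ighm (5.29) and Cxcl13 (5.17) lay below knockout 1 (5.52 and 5.29), so carried-over node stays open although the dissection excluded it. Milk gene expression stays open too, since the lowest wild-type minus the highest knockout mean of Csn1s1, Csn1s2a and Csn2 was -1.01, within 2 SDs of the wild type. Casein means of wild type 1 and 3 (7.91 and 7.35) lay above knockout 1 and 2 (5.85 and 3.23). That of wild type 2 (4.83, with Glycam1 at 10.74) lay below knockout 1, so Glycam1 did not follow the caseins on every array. The genotype stays open as well, untested beyond limma's adjusted p = 0.919.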
